A study of Rattus norvegicus with 4 samples.

How the data were processed

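Libraries were made from poly(A) RNA, after DNase treatment, with a stranded mRNA kit that keeps the strand of each transcript, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, fastp 0.20, STAR 2.7a and edgeR 3.30.3 and the genome build Rnor_6.0, with no role or order. The counting program, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads from near-identical genes could therefore be split or lost in ways that cannot be seen in the counts. The authors deposited 1 table per library, with a whole-number count per Ensembl gene identifier and no normalization. The tables hold the same 22281 identifiers in the same order, and 4913 of these had 0 counts in all 4 libraries.

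Samples were grouped from their titles, as 1 rESC and 3 rTTF libraries, and strain was taken from the characteristics. Labels call the rTTF libraries biological replicates but do not name the animals, so p-values measure the spread between these samples. No pairing exists between the groups, since the rESC group has 1 library.

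Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (two-sided) with TMM factors. The default expression filter kept genes with about 10 counts in at least 1 library, scaled to library size, and at least 15 counts in total. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no fold minimum. The model for rESC against rTTF held all 4 libraries and no covariate, leaving 2 residual degrees of freedom. The common biological coefficient of variation was 0.314. The Sprague Dawley library was tested against both Brown Norway libraries in the same way, with 1 residual degree of freedom. CPM were computed by total count for detection and shares, and by TMM-scaled library size for the levels of genes in the comparison. Correlations used log2 CPM with a prior count of 2. A gene with 0 counts was given a floor of 3 counts per library, which is 0.0992 TMM-scaled CPM in rESC and up to 0.130 in rTTF. Intervals of single shares are 95% Wilson intervals.

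These designs, a rule for naming genes, 34 gene lists and most alternatives were fixed before the data were examined. The alternatives chosen afterwards are named where their results are given. The files give identifiers without names, and the gene table at hand holds an Ensembl identifier in 0 of its rows, so none of the 22281 identifiers could be looked up. The gene lists, their set tests and the levels of HOX genes were therefore not analysed here. From the naming rule, the part for the largest changes at 100 CPM or more was applied to identifiers and limited to 2 per direction; its exclusion of genes without a symbol was dropped.

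The procedure was tested on simulated data, drawn from the real mean counts and library sizes with the dispersion of the rTTF libraries and 200 changed genes. For rESC against rTTF (14145 genes tested), 81 of 100 genes changed 8-fold and 5 of 100 changed 2-fold were recovered, with 9 calls among unchanged genes. For the strain comparison (12905 genes tested), 83 of 100 genes changed 8-fold and 13 of 100 changed 2-fold were recovered, with 1 call among unchanged genes. Most simulated 2-fold changes were missed. Simulated rESC counts were drawn with the rTTF dispersion. The calls among unchanged genes therefore cannot check whether a real rESC library varies like the rTTF libraries. Simulated genes of similar abundance shared the same dispersion, while real genes can differ in theirs. The simulated recovery of 8-fold changes therefore does not show what the real strain comparison could find. The real comparison of rESC with rTTF called 8227 genes, of which 1047 higher and 681 lower had fitted changes under 2-fold, so the simulated recovery does not describe what that comparison misses. In the real comparison the median standard error of log2 fold change, taken from the F statistic, was 1.26 for genes under 1 CPM, 0.670 from 1 to 10 CPM, 0.213 from 10 to 100 CPM, 0.168 from 100 to 1000 CPM and 0.298 over 1000 CPM, by the higher group mean.

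Alternatives were DESeq2 1.42.0, limma 3.58.1 with voom, edgeR's likelihood ratio test, other scaling factors, other filters on low counts, a fold minimum, the strains as separate groups, and leaving out each rTTF library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.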

Results

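Poly(A) RNA was sequenced from 4 rat cell samples. One library came from a rat embryonic stem cell line of the Dark Agouti strain (rESC), a pluripotent line obtained from a repository. The other 3 libraries came from tail tip fibroblasts (rTTF), connective tissue cells from the tail of adult rats; replicates 1 and 2 were from Brown Norway rats and replicate 3 was from a Sprague Dawley rat. The rTTF libraries are called biological replicates by the submitters, and the rESC library has no replicate. The deposited values were raw counts for 22281 Ensembl rat gene identifiers, of which 17368 had at least 1 count in at least 1 library. The total count was 23638751 in rESC, 34297606 in rTTF replicate 1, 28010124 in replicate 2 and 26326230 in replicate 3. Neither the count files nor the gene table used here paired these identifiers with gene names, so genes are described below as groups defined by their level and change, and 4 identifiers are given as examples. The pathway, cell type marker and HOX gene lists fixed for these cells could not be applied for the same reason.

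The first question was which genes each kind of cell expressed. The rESC library contained more expressed genes than any fibroblast library. In rESC, 12329 genes reached 1 CPM (the count scaled to the library total), against 11531 ± 47.8 in rTTF (SD, n = 3), where the libraries ranged from 11487 to 11582. A shared set of 10423 genes reached 1 CPM in all 4 libraries. A further 1452 genes reached it in rESC and in no rTTF library, while 1128 genes reached it in at least 1 rTTF library and not in rESC, 661 of them in all 3 rTTF libraries. By comparison, 100 genes reached 1 CPM in rTTF replicate 1 alone, 104 in replicate 2 alone and 68 in replicate 3 alone. By total count, the rESC library also had more genes at moderately high level. It had 2434 genes at 100 CPM or more, against 1908 ± 98.1 in rTTF (SD, n = 3). At 1000 CPM or more the order was the opposite, with 71 genes in rESC and 104 ± 7.09 in rTTF (SD, n = 3). The TMM factor was 1.28 in rESC and 0.880 to 0.956 in rTTF. TMM scaling thus lowers levels in rESC and raises them in rTTF, against the order at 100 CPM. These counts were not redone with TMM-scaled CPM, so the order at 100 CPM may not hold under it. With 1 rESC library these differences can be set only against the spread of the fibroblast libraries, and no test was made of them.

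Counts were less concentrated in abundant genes in rESC than in fibroblasts. The most abundant gene held 1.10% of the rESC counts (95% Wilson interval 1.10% to 1.11%) and 3.47% ± 1.26 of the rTTF counts (SD, n = 3). The 10 most abundant genes of each library held 5.49% of counts in rESC (95% Wilson interval 5.48% to 5.49%) and 12.4% ± 3.33 in rTTF (SD, n = 3). The 100 most abundant genes of each library held 18.71% in rESC (95% Wilson interval 18.69% to 18.72%) and 29.5% ± 2.84 in rTTF (SD, n = 3). The identity of the abundant genes also differed. Between 80 and 85 of the 100 most abundant genes were shared by any pair of rTTF libraries, whereas rESC shared 29 to 32 of its 100 with each rTTF library. Wilson intervals here cover counting error only, since reads are not independent molecules.

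**Figure D1:**
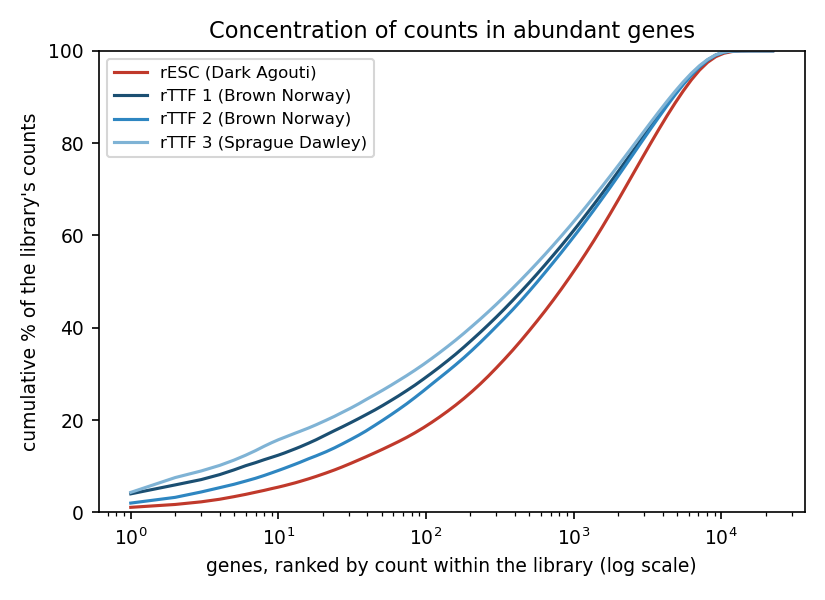
Cumulative percentage of a library's counts (vertical axis) held by its genes ranked from most to least abundant (horizontal axis, log scale), 1 line per library. At rank 100 the rESC line stands at 18.7% and the rTTF lines lie between 26.8% and 32.5%.

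The main comparison asked how gene expression differed between pluripotent cells and fibroblasts. Of 14346 genes tested with edgeR's quasi-likelihood test, 8227 (57.3%) passed an adjusted p of 0.05 (Benjamini-Hochberg), 4294 of them higher in rESC and 3933 lower. The share called was 45.1% without rTTF replicate 3, 45.9% without replicate 1, 49.0% with the strains as separate groups, 46.2% without a filter on low counts and 30.0% when a fold above 2 was required. It was 51.6% without replicate 2 and 57.6% to 67.5% with the other tools, scalings and filters. The genes higher in rESC held 46.70% of the rESC counts (95% Wilson interval 46.68% to 46.72%) and 13.3% ± 0.824 of the rTTF counts (SD, n = 3). The genes lower in rESC held 15.01% of the rESC counts (95% Wilson interval 14.99% to 15.02%) and 59.6% ± 2.11 of the rTTF counts (SD, n = 3). The changes among called genes were large. These genes were picked by the test in these same libraries, so their folds and shares of counts describe the calls and are not independent evidence. Among genes higher in rESC the median log2 fold change was 1.70 (quartiles 1.01 and 4.35), 3247 differed by at least 2-fold and 935 by at least 32-fold. Among genes lower in rESC the median absolute log2 fold change was 2.13 (quartiles 1.22 and 4.06), 3252 differed by at least 2-fold and 696 by at least 32-fold. Fitted folds of genes without counts in 1 of the groups depend on a prior count; this applied to 327 of the higher and 119 of the lower genes.

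Abundant genes with large changes were mostly lower in rESC. A group of 229 genes was at 100 CPM or more in rTTF and at least 32-fold lower in rESC; it held 20.4% ± 2.42 of the rTTF counts (SD, n = 3) and 0.272% of the rESC counts (95% Wilson interval 0.270% to 0.274%). The converse group, at 100 CPM or more in rESC and at least 32-fold higher there, had 70 genes and held 2.06% of the rESC counts (95% Wilson interval 2.06% to 2.07%). The asymmetry held with each rTTF library left out, with 228 to 233 genes lower and 67 to 75 higher. It was smaller when libraries were scaled by total count alone, with 186 genes lower and 101 higher. Among genes at 1000 CPM or more in the group with the higher level, 85 were lower and 17 higher in rESC. Of the 100 genes most abundant in rTTF, 72 were lower in rESC, 40 of these by at least 32-fold, 3 were higher and 25 did not pass the test. Of the 100 most abundant in rESC, 40 were higher there, 2 of these by at least 32-fold, 4 were lower and 56 did not pass. Both lists and the groups above were picked by their level or change in these libraries, so they are not independent evidence of direction. The split at 1000 CPM and the calls in both lists used TMM factors and were not recounted by total count alone. A group of 672 genes at 100 CPM or more in either kind of cell did not pass the test, and 625 of these differed by at most 2-fold.

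**Figure D2:**
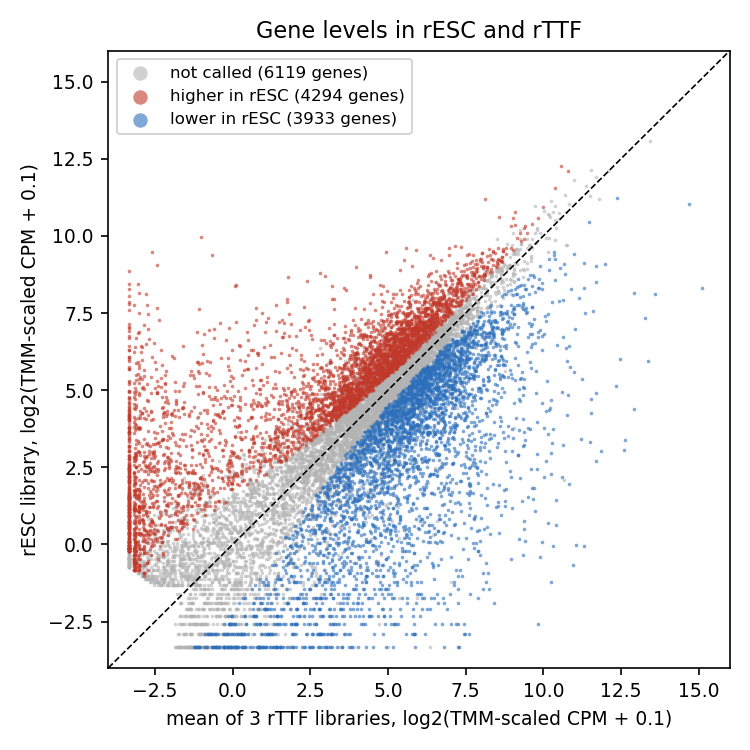
Each point is 1 of the 14346 tested genes, with its mean level in the 3 rTTF libraries (horizontal axis) and its level in the rESC library (vertical axis), both as log2 of TMM-scaled CPM with 0.1 added; the dashed line marks equal levels. Red points are the 4294 genes higher in rESC, blue points the 3933 lower and grey points the 6119 that did not pass an adjusted p of 0.05.

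The 4 identifiers given as examples had the largest fitted changes, 2 in each direction, among called genes at 100 CPM or more in the group with the higher level. Each had 0 counts in the other group, where fitted changes depend on the prior count, so this is not an order by measured fold. For the 2 higher in rESC, the rTTF libraries show no spread. The adjusted p-values of these 2 identifiers therefore rest on dispersion estimated over other genes. ENSRNOG00000050670 was at 468 TMM-scaled CPM in rESC and had 0 counts in each rTTF library, which makes it at least 3615-fold higher in rESC against a floor of 3 counts in the shallowest rTTF library by effective size (adjusted p = 0.00188, edgeR). ENSRNOG00000008368 was at 350 TMM-scaled CPM in rESC with 0 counts in each rTTF library, at least 2701-fold higher (adjusted p = 0.00190, edgeR). ENSRNOG00000010797 was at 151 ± 44.6 TMM-scaled CPM in rTTF (SD, n = 3) and had 0 counts in rESC, at least 1524-fold lower in rESC against a floor of 3 counts there (adjusted p = 0.00170, edgeR). ENSRNOG00000002555 was at 156 ± 166 TMM-scaled CPM in rTTF (SD, n = 3) with 0 counts in rESC, at least 1570-fold lower by the mean of all 3 libraries and at least 607-fold lower without replicate 1 (adjusted p = 0.0250, edgeR). Its rTTF libraries stood far apart, at 347, 78.2 and 42.1 TMM-scaled CPM in replicates 1, 2 and 3, and its call was lost with limma's voom (adjusted p = 0.211).

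The spread behind these tests came from the 3 rTTF libraries alone (2 residual degrees of freedom). The single rESC library was assumed to vary like them, which the data cannot check. Genes with 0 counts in each rTTF library show no spread of their own. The p-values of such genes rest on dispersion estimated over other genes. Strain differed along with cell type, since no fibroblast library was Dark Agouti, so the 2 cannot be told apart. The balance between higher and lower calls depended on the processing. Of the calls, 52.2% were higher in rESC in the reported test, 49.3% with DESeq2 (4190 higher and 4306 lower) and 47.4% when a fold above 2 was required. The share was 49.9% without rTTF replicate 1 and 49.8% without replicate 2. It was 50.7% to 57.8% with voom, the likelihood ratio test, RLE or upper quartile factors, no filter, the strains as separate groups or rTTF replicate 3 left out. It was 67.2% with library size alone, which raised the median log2 fold change of all tested genes by 0.47. Filters requiring 1 CPM in 3 libraries or a mean of 10 CPM over all 4 gave 49.8% and 50.8%, but with 1 rESC library they remove more readily the genes expressed in rESC alone, so these shares do not bear on the balance.

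The fibroblast libraries were then compared with each other, to see how far replicates from 2 strains differed. Across the 14346 genes, log2 CPM correlated between rTTF libraries with Pearson's r of 0.971 to 0.976 and Spearman's rho of 0.979 to 0.982. Between rESC and the rTTF libraries, r was 0.648 to 0.652 and rho 0.696 to 0.702. Among genes with a mean of at least 10 CPM, the highest r between rESC and an rTTF library was 0.274, against a lowest r of 0.962 between rTTF libraries. That filter was set on these same libraries and removes genes low in both kinds of cell. This narrows the range of levels and can lower r by itself, so 0.274 is not a measure of greater unlikeness. These are correlations across genes, which are not independent replicates. Between 11.2% and 12.9% of the genes differed by more than 2-fold between a pair of rTTF libraries, against 56.6% to 57.0% between rESC and an rTTF library. All pairs of libraries differed by more than the sampling noise of their counts, with a chi-square per degree of freedom between 123 and 1177, so no pair of files held the same reads; this does not tell separate animals from separate preparations.

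Setting the Sprague Dawley library against both Brown Norway libraries, edgeR's quasi-likelihood test called 0 of 12922 genes, and the smallest adjusted p was 0.876. At an unadjusted p under 0.05 there were 634 genes, or 4.91% of those tested. The Wald test of DESeq2 called 76 genes, edgeR's likelihood ratio test 104 and limma's voom 0. Among the splits of these libraries into a single library and the remaining pair, the split by strain gave the fewest calls with DESeq2 and the likelihood ratio test. At an unadjusted p under 0.05 in the quasi-likelihood test, the split by replicate 1 gave fewer genes than the split by strain. The order of the splits thus depended on the test. With 1 Sprague Dawley library, strain cannot be told apart from animal, and the spread came from 1 residual degree of freedom. The absence of calls in the quasi-likelihood test therefore does not show that the strains are alike.

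**Figure D3:**
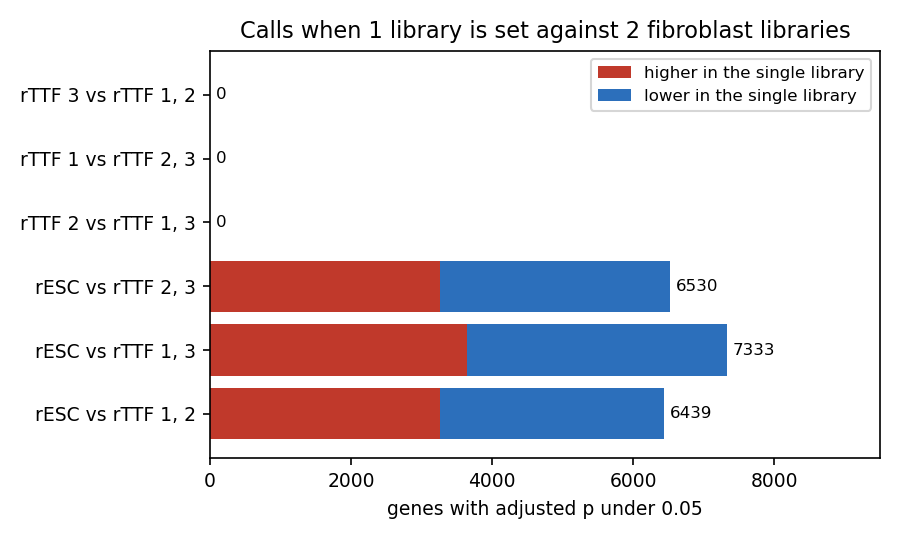
Number of genes passing an adjusted p of 0.05 in edgeR's quasi-likelihood test (horizontal axis) when 1 library was set against 2 rTTF libraries (vertical axis), split into genes higher (red) and lower (blue) in the single library. The 3 splits among rTTF libraries gave 0 genes each and the rESC library gave 6439 to 7333.

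At this same size of 1 library against 2, rESC differed from each pair of rTTF libraries in 6439 to 7333 genes, while each of the 3 splits among rTTF libraries gave 0 genes with the same edgeR test. Individual genes still varied among the fibroblasts. Of 12922 genes, 2520 (19.5%) differed by more than 2-fold between at least 1 pair of rTTF libraries and 372 by more than 8-fold. No minimum level beyond the expression filter was set, so counting noise in genes with few counts can add to these numbers. Among these 2520 genes, the library farthest from the mean of the other pair was replicate 2 for 996 genes, replicate 1 for 774 and replicate 3 for 750.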

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

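For rESC against rTTF, the number of genes called stayed within 1.5 times the 8227 of the reported test under every other tool, scaling and filter run, and under the strains as separate groups (6160 to 8741 genes). Requiring a fold above 2 gave 4298 genes, 2037 higher and 2261 lower; this test asks for more than a difference from 0. Leaving out rTTF replicates 1, 2 and 3 in turn gave 6530, 7333 and 6439 genes. Genes called both in the reported test and in an alternative never differed in direction. Library size alone kept 7159 of the 8227. Fewer were kept with the strains as separate groups or with any rTTF library left out. The stricter filters on low counts also kept fewer, partly because they left some of these genes untested. The fewest were kept where a fold above 2 was required. Of the 4 identifiers, ENSRNOG00000002555 lost its call with voom, and its adjusted p otherwise stayed under 0.05; ENSRNOG00000050670 and ENSRNOG00000008368 were not tested where 1 CPM was required in 3 libraries, which removes genes found in rESC alone. For Sprague Dawley against Brown Norway, 0 genes were called under RLE factors, library size alone, no filter and voom. DESeq2 called 76 (37 higher, 39 lower) and the likelihood ratio test 104 (66 higher, 38 lower); the cause was not tested. The lowest correlation between rTTF libraries (0.971) became 0.962 at a mean of at least 10 CPM and 0.963 at a prior count of 0.5. The highest between rESC and rTTF (0.652) became 0.274 and 0.617. The filter at 10 CPM removes genes low in both kinds of cell, which can lower r by itself. How much of the fall it accounts for was not tested. The 1452 genes found in rESC alone became 1582 at 0.5 CPM, 1212 at 5 CPM, 1221 with TMM-scaled CPM and an expected 1438 with totals thinned to the smallest, alternatives chosen after seeing the data, as was leaving out the 100 genes most abundant in rTTF. Alternatives for gene lists and HOX genes were not run for lack of gene names. By the higher group mean, 20.05% of genes under 1 CPM passed the test, 77.1% at 100 to 1000 CPM and 73.9% above; depth was not varied in the test, so its part in this was not tested.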

Other observations

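The tests of depth, of an even background and of a share of fibroblast RNA were chosen after their results were partly seen; both tests that leave out abundant genes were stated before they were run.

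The rESC library had the smallest total count and the most expressed genes. Of 6249 identifiers with 0 counts in all rTTF libraries, 1336 had counts in rESC and 318 of these reached 1 CPM. A difference in depth is argued against, since rESC had 16282 genes with any count, against 14881 ± 186 in the deeper rTTF libraries (SD, n = 3). Thinning to the rESC total, which leaves rESC as it was and moved the rTTF mean only from 11531 to 11543 genes, kept an excess of 737 genes at 1 CPM over the highest rTTF library (SD 49.2). The concentration of counts in each library's 100 most abundant genes is also argued against as the whole cause. Without these genes an excess of 699 genes remained (SD among rTTF libraries 26.3). The excess was not recounted with TMM-scaled CPM, under which the genes found in rESC alone fell from 1452 to 1221. A wider effect of scaling on the excess therefore stays open. An even background strong enough to lift genes to 1 CPM would leave few genes uncounted, yet 78.6% of the genes at 0 in rTTF were also at 0 in rESC. Some of these identifiers may be unable to receive reads, but another 1086 at 0 in rESC had counts in rTTF. A lighter background could still raise the number of genes with any count and was not tested. A broader transcriptome of the stem cells, strain, culture and chance in a single rESC library stay open and were not tested.

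The split of calls between higher and lower moved with scaling, among other settings, and for scaling the counts taken by abundant fibroblast genes are a candidate explanation. The 100 genes most abundant in rTTF held 29.1% ± 2.89 of rTTF counts (SD, n = 3) and 11.3% of rESC counts. Without them, library-size scaling gave a median log2 fold change of 0.20, which is 0.15 above the 0.05 of TMM, where all genes together had given 0.47 above it. This falls between the bounds set beforehand, 0.1 for these genes as the whole cause and 0.3 against them, so they cannot be told apart from a broader shift. No spike-in values were used here, so the scalings were not ranked.

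Genes abundant in fibroblasts kept some reads in rESC. The 955 genes that were at 100 CPM or more in each rTTF library and called lower in rESC still held 10.2% of rESC counts. The same genes held 48.0% of rTTF counts on average, and the median ratio of their rESC to rTTF level was 32.1%. Fibroblast RNA mixed into the rESC library at one share is argued against as the main source. The ratio of rESC to rTTF level ran from 0.521% at the 5th percentile of these genes to 57.3% at the upper quartile. A share of 0.521% would supply 2.45% of their rESC counts. Expression by the stem cells themselves, or cells with another profile in the culture, stays open and was not tested.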
